A study of Mus musculus with 71 samples.

How the data were processed

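The deposited table gives 1 intensity per probe set and array for 71 oligonucleotide arrays of 45101 probe sets, hybridised with labelled RNA from mouse brain. Per the submitters' processing notes, the values were made with GCRMA, which corrects background by probe sequence, normalizes and summarises probes into probe sets; its version, and which arrays were processed together, are not given in the sources used here. The deposited intensities were on a linear scale, with a lowest value of 0.0271, and every array had a median of 1, so the authors' values are relative to the array median; array maxima ranged from 879.3 to 2816. Per the series design, mice were 10 to 14 weeks old, while the extraction protocol in the labels gives 12 weeks for the mice whose tissues were taken. Per the labels' protocols, controls were littermates matched for age and sex, RNA was amplified over a pair of cycles, and each polyribosome sample pooled 5 mice. A further genotype named in the protocols, lacking both enzymes, was not analysed here. Groups, replicate numbers and tissues were taken from the sample titles and source names. For 1 G9a hypothalamus control the title gives number 4 and the source name mouse 5, and the title was followed. The labels call the replicates biological. The p-values measure the spread of arrays around their group means, pooled per gene over all groups of a fit. They do not measure the spread within the compared groups alone. Whether regions share animals is not given in the sources used here. The number of arrays per group limits the precision of each value.

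Values were used as log2 without a floor, so 0 is the median of an array. Of the probe sets, 64 controls were left out, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 were not in that table and stayed unnamed. Entrez identifiers of 34754 matched a RefSeq gene table, which changed 0 symbols. Each of 18194 genes was represented by its probe set of highest mean over the arrays of the fit. A gene was tested where its log2 value was above 0 in at least as many compared arrays as the smaller group holds. A gene below 0 in every control was therefore tested only where it lay above 0 in mutants, which favours rises in lists of such genes. The design had set this filter at a log2 value of 5 and a floor at 1 for values not scaled to the median. As the values are scaled, that filter would keep only genes over 32 times the array median, so both were replaced before any test was run and kept as alternatives chosen after seeing the data. No pair of arrays was a duplicate: the highest correlation was 0.998 and at most 4.74% of probe sets had identical values in 2 arrays.

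Group means were fitted with limma 3.58.1 in R 4.3.3, the 16 whole-tissue groups in 1 fit and the 4 polyribosome groups in another, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment per comparison at 0.05. Apart from the filter, the floor and the alternatives described below as added later, the design, alternatives, gene lists and naming rule were fixed before the data were examined. Interactions tested whether the change on loss of GLP differed from that on loss of G9a, or that in Drd1-MSN from that in Drd2-MSN, and a moderated F test compared the change across 4 regions. Overlaps of called genes were set against the product of the list sizes over the genes tested in both, per direction, by two-sided Fisher exact tests adjusted over 19 pairs. The GLP and G9a comparisons have separate controls. Gene lists, 35 in all and drawn up from general knowledge of brain cell types, pathways and the neighbours of the driver and target genes, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry; a list needed 3 measured genes, and the sex-linked list was used only to check sex.

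Named in the text were, among called genes whose arrays do not overlap, up to 12 with the largest rise and 8 with the largest fall per comparison, Ehmt1 and Ehmt2, up to 4 called members per list, called neighbours of the driver genes, the 5 smallest p where under 5 genes passed, the 20 genes called in the most comparisons, and the 6 smallest p per interaction; genes known only by a clone name were counted and not named. The 24 kidney markers and the 50 cortex genes of the closing section were chosen after the data were examined. The fit was tested on simulated data made from the real group means. For the GLP hippocampus, with 11674 genes, it recovered 97% of genes changed by 1 and 99% of those changed by 2 on the log2 scale, with 5.77% of calls false. For the G9a cortex, with 11686 genes, these were 83%, 98% and 5.73%. They were 17.2%, 70.7% and 9.38% for Drd1-MSN, with 12225 genes, and 18%, 72% and 5.26% for Drd2-MSN, with 12181 genes. The simulated noise was independent between arrays and genes, with the same SD per gene in every group. Real groups differed in spread: the mean SD of differences from the group was 0.32 in G9a hypothalamus mutants and 0.15 in GLP cortex mutants. These rates therefore need not hold for the real arrays.

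Whether equal replicate numbers pair mutant with control arrays was checked by the correlation of their deviations from group means, across genes. In Drd2-MSN all 3 pairs were over 0.1 (0.168 to 0.482), and in no other comparison were all pairs. Alternatives were all probe sets, no filter, no intensity trend, only the compared groups in the fit, quantile normalization, the replicate number as a block, a random block for arrays of equal number across regions, a sex covariate, a fold of at least 1.5, and leaving out each array in turn. Leaving out arrays of high Gapdh 3-prime to 5-prime ratio or far from their group was added after seeing the data.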

Results

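Messenger RNA was profiled on 71 oligonucleotide arrays from the brains of mice lacking GLP (gene Ehmt1) or G9a (gene Ehmt2), the partner enzymes that place mono- and dimethyl marks on lysine 9 of histone H3. In 59 of these arrays, in 16 groups, each enzyme was deleted by Cre recombinase driven by the Camk2a promoter, which is active in forebrain neurons after birth. Total RNA came from the hippocampus, hypothalamus, striatum or cortex of mutants and floxed littermates. Each of these groups held 4 arrays, except the G9a hippocampus controls with 3 and the G9a cortex mutants and controls with 2 each. The other 12 arrays, in 4 groups of 3, held messenger RNA from polyribosomes pulled down through a tagged ribosomal protein in striatal medium spiny neurons (MSN) that express the dopamine receptor Drd1 or Drd2, from pools of 5 mice labelled as with or without deletion of G9a in that cell type. The design asks which genes each enzyme holds down in each region or cell type, and whether loss of either enzyme moves the same genes. The number of arrays limits the precision of each value. Whether separate regions were taken from the same mice is not given in the sources used here.

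Changes below are log2 differences of group means with their standard error (SE) from limma, and adjusted p is Benjamini-Hochberg adjusted over the genes tested in that comparison. Where the lower group lay below the median of its arrays, the fold is a lower bound taken from that median, written as "at least". The log2 changes of such genes rest on dim signals, and the bound is what the arrays support. For each gene listed among the rises and falls of a comparison, every mutant array lay on the same side of every control array. With only genes over 32 times the array median tested, a filter chosen before the values were known to be scaled, the mutant comparisons called between 1 and 58 genes.

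The deleted genes were read first. Ehmt1, with 1 probe set, stood at 58.9% of control in the GLP cortex (adjusted p = 6.27e-06), 67.0% in the hippocampus (adjusted p = 0.000914) and 72.6% in the striatum (adjusted p = 0.0178, a call lost without any 1 of 4 arrays). In the GLP hypothalamus it stood at 89.8% and did not pass the test (adjusted p = 0.713). The brighter of 2 Ehmt2 probe sets fell to 29.5% of control in the G9a cortex, 41.1% in the striatum, 44.6% in the hippocampus and 49.2% in the hypothalamus, with a highest adjusted p of 1.44e-06. In the Drd1-MSN pools labelled mutant it stood at 24.3% of control, a log2 difference of -2.04 (SE 0.75) that did not pass (adjusted p = 0.942). That difference rested largely on mutant 2, at 1.56 on the log2 scale where mutants 1 and 3 lay at 5.01 and 4.93 and the controls at 5.49 to 6.22, and without mutant 2 it was -0.91. In the Drd2-MSN pools labelled mutant it stood at 94.5%, a log2 difference of -0.08 (SE 0.75). As this probe set fell in all 4 G9a tissues, that level goes against the label mutant, although the SE leaves room for a fall as in the hypothalamus (-1.02). The Drd2-MSN controls scattered, with an SD of 0.88 against 0.065 in the pools labelled mutant. Afp and Dach2 were higher in those pools by 6.66 and 3.74, as in the G9a striatum (6.41 and 5.99), which goes with the label. The dimmer Ehmt2 probe set, read in a fit of all probe sets, lay near or below the array median and passed in no comparison. Whether these probe sets lie inside the deleted exons is not given in the sources used here.

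**Figure D1:**
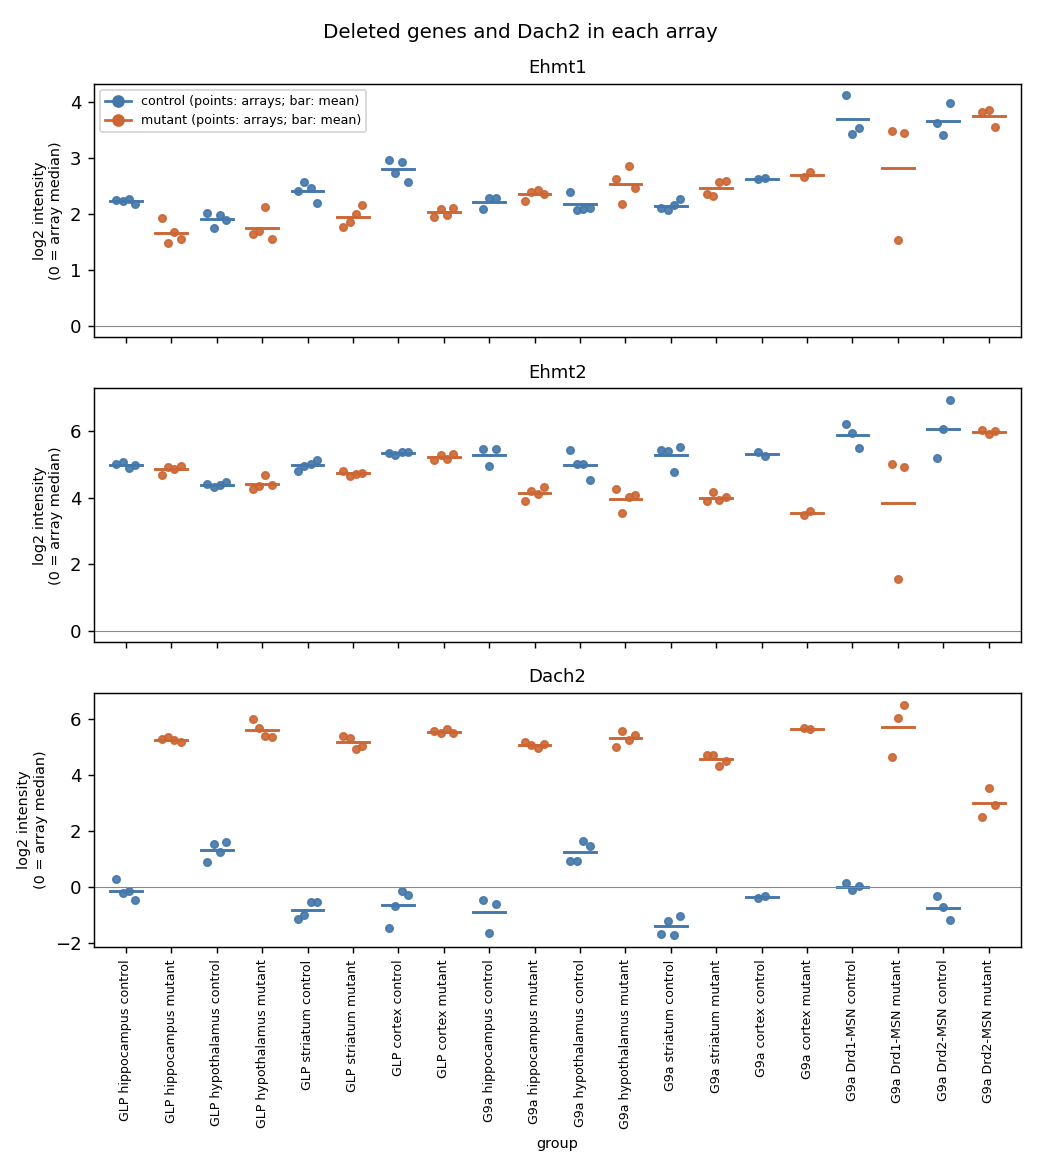
Log2 intensity relative to the array median (y axis) of Ehmt1, Ehmt2 and Dach2 in each array (points) of the 20 groups (x axis), with group means as bars and control and mutant in different colours. Ehmt2 was 29.5% to 49.2% of control in the 4 G9a tissues, and Dach2 was higher in the arrays labelled mutant of all 10 comparisons, among them the Drd2-MSN pools, where Ehmt2 stood at 94.5%.

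Dach2, a transcription cofactor of the dachshund family, rose in all 10 comparisons of arrays labelled mutant with controls, by a mean of 5.35 on the log2 scale. Its call in Drd2-MSN was lost with pools paired by number as a block. Tnnt2, the troponin T of heart muscle, rose in all 8 tissue comparisons (mean 2.28). So did the secreted glycoprotein gene Olfm4 (1.78), Serpinb1b (1.71), Ifitm2 (1.02), Gstm7 (0.91) and Ces5a (0.70). Ces5a lost its call without any 1 of the 4 arrays of the G9a cortex, 5 of the GLP striatum or 2 of the G9a hypothalamus, and Ifitm2 without any 1 of 5 arrays of the G9a striatum, 4 of the G9a hypothalamus or 2 of the G9a cortex. Amn, a partner of cubilin in uptake by kidney and gut epithelium, fell in all 8 tissue comparisons (mean -1.73). Its call in the GLP hypothalamus was lost in 3 other settings and without any 1 of 5 arrays. Slc5a5, the iodide transporter of the thyroid, fell in 7 (mean -1.46). The myosin and M-band genes Myh7 and Myom2 rose in 7 tissue comparisons, with Casp1, Pgam2, Dnah1, Tfpi and Lipo3. Lipo3 lost its call in the G9a striatum without any 1 of 7 arrays and Tfpi in the GLP hypothalamus without any 1 of 4. Afp, the fetal plasma protein alpha-fetoprotein, rose in 6 of the 10 comparisons (mean 5.37), as did Defb1, Gsta2 and Bank1. Kdm3b, a demethylase of lysine 9 of histone H3, and Reep6 fell in 6. Kdm3b lost its call in the G9a hippocampus in 5 other settings and without any 1 of 6 arrays, in the G9a cortex without any 1 of 4 and in the GLP hippocampus without any 1 of 3. Calls were also lost without any 1 of 3 arrays for Casp1 in the GLP hippocampus, Myh7 in the GLP striatum and Pgam2 in the G9a cortex. The same held without either of 2 arrays for Gstm7 in the G9a cortex and GLP striatum and Slc5a5 in the G9a cortex, and without 1 array for Reep6 and Serpinb1b there. Over the 10 comparisons 808 genes rose and 311 fell at least once. Of these, 76 rose and 16 fell in at least 4 comparisons, while 571 rose and 251 fell in exactly 1. In addition, 11 genes rose in one comparison and fell in another.

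**Figure D2:**
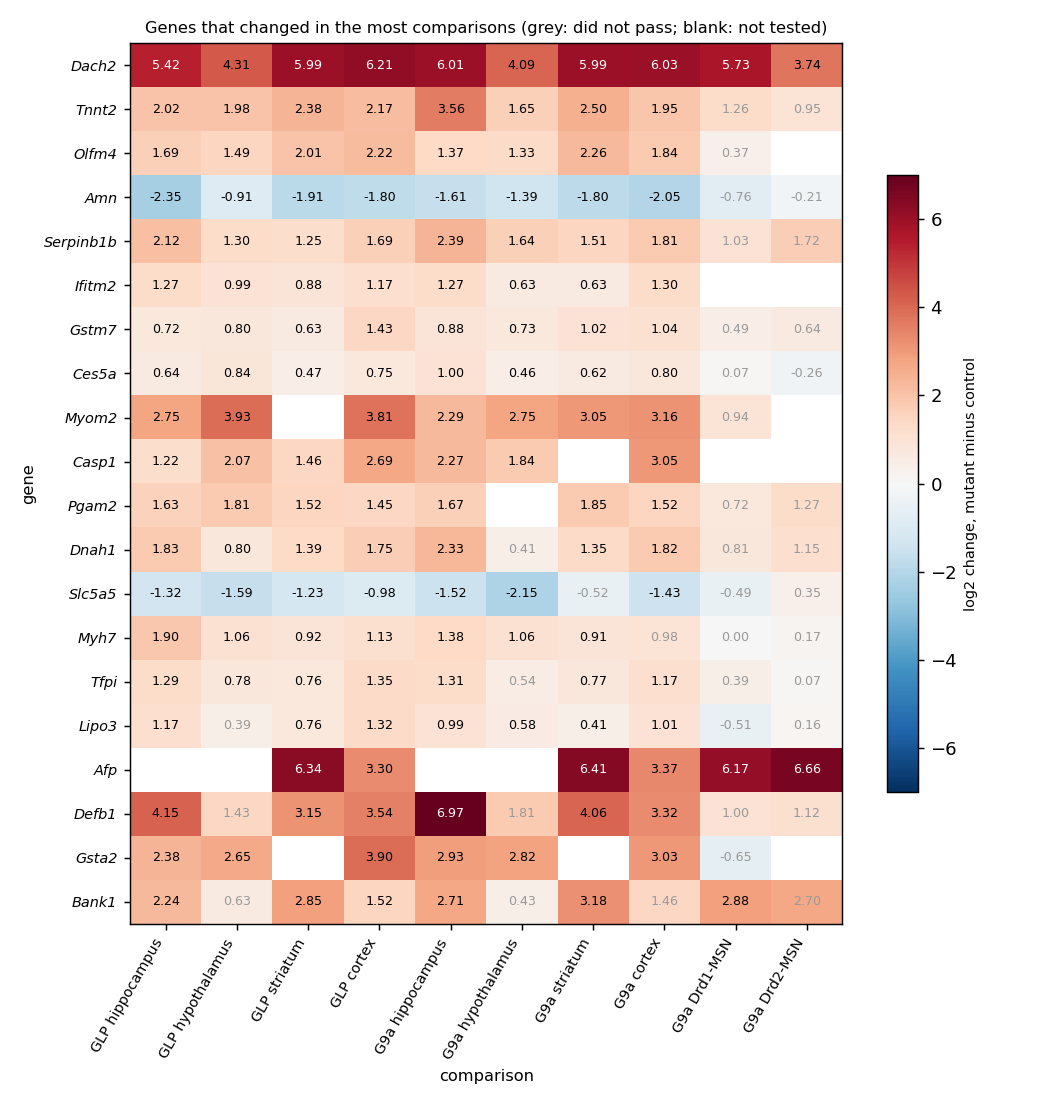
Log2 change, arrays labelled mutant minus controls (colour scale and printed values), of the genes that changed most often (y axis) in the 10 comparisons (x axis); cells of genes not tested in a comparison are blank and values that did not pass limma's test are printed in grey. Dach2 rose in all 10, and Amn fell in all 8 tissue comparisons. The calls of Dach2 in Drd2-MSN and of Amn in the GLP hypothalamus were lost in some other settings.

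In the GLP hippocampus, 4 mutants against 4 controls, genes of the choroid plexus and of muscle rose. Dach2 rose at least 38.6-fold (log2 change 5.42, SE 0.22, adjusted p = 1.75e-25), the cystatin gene Cst12 at least 4.35-fold (4.89, SE 0.32) and Defb1, an antimicrobial defensin, at least 8.35-fold (4.15, SE 0.54). Gpr50, a receptor related to those of melatonin, rose at least 4.37-fold, Mettl24 at least 8.16-fold, the coagulation factor gene F5 at least 4.55-fold and the protease gene Tmprss11a at least 3.78-fold. Amn had the largest fall, at least 3.43-fold (log2 -2.35, SE 0.24, adjusted p = 6.12e-10), followed by Slc5a5 (-1.32, SE 0.20), the activin antagonist Fst (-1.26, SE 0.29), Ntn5 (-1.11), the meiotic gene Syce2 (-0.95), Hapln4 (-0.94, SE 0.16), Arg2 (-0.84) and Flrt3 (-0.82, SE 0.10). In all, 242 of 11685 genes changed, 205 up and 37 down.

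Of 21 choroid plexus and ependymal markers measured in that comparison, 16 rose and 0 fell (17 rose when adjusted over the list alone), with a median log2 change of 2.21 (camera adjusted p = 5.88e-38; adjusted p = 0.00202 with an estimated correlation). They included the potassium channel genes Kcne2 (11.5-fold) and Kcnj13 (9.33-fold, a call lost without any 1 of 5 arrays), the folate receptor gene Folr1 (11.1-fold) and the water channel gene Aqp1 (at least 3.81-fold). The tight junction gene Cldn2, which is not in that list, rose 14.5-fold (log2 3.85, SE 0.70). The mean of these markers differed between control arrays, at 2.49, 0.94, 0.81 and 2.19 on the log2 scale, and lay between 3.18 and 3.74 in the mutants. Of 13 muscle genes 4 rose and 0 fell (adjusted p = 4.27e-08; 0.000287 with an estimated correlation), namely the myosin heavy chain genes Myh1 (at least 2.83-fold), Myh7 (3.72-fold) and Myh8 and the troponin gene Tnnt2 (4.07-fold). Arsi, 1 of 11 measured genes that lie next to Camk2a on the chromosome, rose 6.14-fold (log2 2.62, SE 0.38, adjusted p = 2.93e-06). That list was called with 1 of its genes up, or 3 when adjusted over the list alone (adjusted p = 0.0482; adjusted p = 0.563 with an estimated correlation). Its mean change was 0.40 while its median was -0.0045.

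Other lists moved by less in the GLP hippocampus. Of 25 genes of the H3K9 methylation machinery 3 fell, namely Ehmt1 (-0.58, SE 0.12), Kdm3b (-0.41) and Kdm3a (-0.36; list adjusted p = 0.0286; adjusted p = 0.521 with an estimated correlation). That list holds both target genes, so the deletion itself adds to its fall, and its median change was -0.036. Kdm3a lost its call in 3 other settings and without any 1 of 5 arrays. Meningeal and fibroblast markers had 1 of 21 up, the fetal growth factor gene Igf2 (1.16, SE 0.32, adjusted p = 0.033), which lost its call without any 1 of 6 arrays, or 4 when adjusted over the list alone (adjusted p = 0.0489; adjusted p = 0.754 with an estimated correlation). Microglia and macrophage markers had 1 of 21 up, Lyz2 (0.78, a call likewise lost without any 1 of 6 arrays), or 2 when adjusted over the list alone (adjusted p = 0.00805; adjusted p = 0.721 with an estimated correlation). The astrocyte markers, with 0 of 21 members passing, were called up as a list (adjusted p = 0.0195; adjusted p = 0.583 with an estimated correlation). Glutamate receptors and postsynaptic scaffolds, with 0 of 35, were called down (adjusted p = 0.0176; adjusted p = 0.563 with an estimated correlation). Tdo2, which opens the tryptophan ring, rose 2.98-fold.

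In the G9a hippocampus, 4 mutants against 3 controls, 323 of 11741 genes changed, 267 up and 56 down. Defb1 rose at least 11.2-fold (log2 6.97, SE 0.58, adjusted p = 4.69e-13), Dach2 at least 34.1-fold (6.01, SE 0.23) and Gpr50 at least 6.28-fold (5.20, SE 0.38). Gprc5d, an orphan receptor, rose at least 1.93-fold (4.51, SE 0.21, adjusted p = 4.93e-23), Tyrp1, an enzyme of melanin synthesis, at least 4.19-fold (4.39, SE 0.45), Mettl24 at least 12.0-fold and Esr1, the estrogen receptor alpha, 9.67-fold (3.27, SE 0.31, adjusted p = 2.51e-11). Falls were led by Fst (3.93-fold, log2 -1.97, SE 0.32, adjusted p = 2.02e-05), Amn (3.05-fold), Slc5a5 (2.86-fold), the nodal antagonist Lefty1 (2.31-fold, log2 -1.21, SE 0.13), Ehmt2 itself, Wnt2 (-1.08, lost without any 1 of 5 arrays), Cldn22 (-1.01) and Lrrc10b (-1.0). Arsi rose 5.85-fold (2.55, SE 0.41), as it did in the GLP mutants. It lies next to Camk2a, whose promoter drives Cre in both deletions. An effect of the driver therefore cannot be told apart from loss of either enzyme for Arsi.

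By list, 5 of 16 muscle genes rose in the G9a hippocampus and 0 fell (adjusted p = 2.44e-06; 0.00327 with an estimated correlation), with Myh1 at least 5.90-fold, Tnnt2 at least 6.38-fold, Myh8 and the acetylcholine receptor subunit Chrna1. Liver and plasma protein genes had 2 of 7 up, or 3 when adjusted over the list alone (adjusted p = 0.000488; 0.00327 with an estimated correlation), namely the gluconeogenic enzyme gene Fbp1 (at least 1.25-fold) and the retinol carrier gene Rbp4 (log2 0.80). Rbp4 lost its call in 6 other settings and without any 1 of 5 arrays. Meningeal and fibroblast markers had 5 of 20 up, or 8 when adjusted over the list alone (adjusted p = 1.89e-06; adjusted p = 0.365 with an estimated correlation), among them the matrix proteoglycan genes Fmod (3.44-fold) and Lum (1.11) and the collagen gene Col1a2 (1.18). Lum lost its call in 6 other settings and Fmod in 3, each also without any 1 of 4 arrays. Endothelial and mural markers had 1 of 21 up, or 4 when adjusted over the list alone (adjusted p = 4.06e-05; adjusted p = 0.365 with an estimated correlation). Interferon-stimulated genes had 2 of 23 up, Iigp1 (1.46) and Ifih1 (0.60, lost without any 1 of 4 arrays), or 3 when adjusted over the list alone (adjusted p = 0.00968; adjusted p = 0.685 with an estimated correlation). Of 34 glutamate receptor and scaffold genes 2 fell, Homer3 (-0.66) and Gria3 (-0.50; list adjusted p = 0.00385; adjusted p = 0.365 with an estimated correlation), and each lost its call without any 1 of 5 arrays. Of 21 microglia and macrophage markers 4 rose, with the scavenger receptor Cd163 at least 1.69-fold (1.73, SE 0.29), while the list was not called (adjusted p = 0.103). Fos, an activity-regulated transcription factor, rose 2.69-fold (1.43, SE 0.40, adjusted p = 0.0381), a call also lost without any 1 of 5 arrays. The count fell to 192 without control 2, to 211 without mutant 4 and to 188 with these 7 arrays alone in the fit.

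The hippocampal lists of GLP and G9a shared 88 genes up, where independent lists would share 3.83, and 17 down, where they would share 0.162 (two-sided Fisher exact test, adjusted p = 2.01e-102 and 9.77e-31). No gene moved in opposite directions. Both deletions used the same driver, so here and in the other regions shared genes do not separate an effect of the driver from that of the enzymes. The correlation of the changes across the 11432 genes tested in both was 0.633, across genes, which are not independent replicates. The difference between the 2 deletions was tested gene by gene as an interaction, and 19 of 12112 genes passed. Gprc5d had a change of 1.71 on loss of GLP, where it lay under the low-value filter, and of 4.51 on loss of G9a (difference -2.80, SE 0.28, adjusted p = 3.6e-09). Tshz2 had changes of -0.31 and 1.84 (adjusted p = 0.000184), Pla2g5, a secreted phospholipase, of 1.17 and -0.44 (adjusted p = 0.000197), Ido2 of 0.92 and 2.95 (adjusted p = 0.000767), where Pla2g5 on loss of G9a and Ido2 on loss of GLP also lay under that filter, and Cobl of -0.50 and 1.24 (adjusted p = 0.00443). Ehmt2 also passed (difference 1.04, SE 0.20, adjusted p = 0.00711). By Xist and Y-linked genes all GLP arrays matched females while the G9a arrays held both sexes, so sex was not balanced in this test. The level of choroid plexus markers was not balanced either. Their mean lay at 0.81 to 2.49 in GLP controls and 3.18 to 3.74 in GLP mutants. In the G9a hippocampus it lay at 0.13 to 0.29 in controls and 0.33 to 0.89 in mutants. How far this enters the 19 genes was not tested. The count was 58 with values below the array median set to it, 37 without a filter, 7 with the compared groups alone in the fit and 1 with the filter at 32 times the median. Leaving out 1 array at a time gave between 8 genes (without G9a control 2) and 39 (without GLP mutant 4), with 30 without GLP control 1, 12 without G9a mutant 1, 11 without GLP mutant 1 or GLP control 3, 10 without GLP mutant 2 and 9 without GLP mutant 3.

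In the GLP hypothalamus, 4 against 4, muscle genes rose. Nxf3, of the nuclear RNA export family, rose at least 4.63-fold (log2 4.57, SE 0.24, adjusted p = 1.84e-20), Adh6b, an alcohol dehydrogenase, at least 5.67-fold (4.30, SE 0.21, adjusted p = 6.36e-22) and Dach2 19.9-fold (4.31, SE 0.22). Cst12 (at least 2.26-fold), the glutathione transferase gene Gsta2 (at least 3.98-fold), Serpina9 (at least 2.04-fold) and Casp1, the interleukin-processing caspase (4.20-fold), also rose. Slc5a5 had the largest fall, at least 2.77-fold (-1.59, SE 0.20, adjusted p = 2.2e-07), followed by the synaptonemal complex gene Sycp3 (2.58-fold, -1.37, SE 0.27), Lrp1b (-1.25, lost without any 1 of 5 arrays), Cda (-1.24), Crlf2 (-1.07), Kazald1 (-1.03), Syce2 (-0.96) and Amn (-0.91, SE 0.24, adjusted p = 0.0481), whose call was lost without any 1 of 5 arrays. Of 11534 genes 118 changed, 96 up and 22 down. The count was 196 without mutant 1, 202 without control 4 and 39 when only these 8 arrays entered the fit.

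Muscle genes had 5 of 14 members up and 0 down in that comparison, or 6 up when adjusted over the list alone (adjusted p = 1.19e-06; 0.00267 with an estimated correlation), with Myh1 at least 4.75-fold (4.34, SE 0.50) and the giant sarcomere protein titin, Ttn, at least 5.92-fold (2.84, SE 0.38). Drd2-MSN markers had 1 of 13 up, or 4 when adjusted over the list alone (adjusted p = 0.0114; 0.0382 with an estimated correlation). Clustered protocadherins, neuronal adhesion genes, had 0 of 12 up, or 4 when adjusted over the list alone (adjusted p = 0.00318; adjusted p = 0.284 with an estimated correlation). Meningeal and fibroblast markers had 2 of 19 up, or 4 when adjusted over the list alone (adjusted p = 0.0138; adjusted p = 0.651 with an estimated correlation), including the collagen gene Col6a3 (2.98-fold). Cytosolic ribosomal proteins, with 0 of 44 members passing, and the mitochondrial respiratory chain, with 0 of 87, were called down as lists (adjusted p = 0.000144 and 4.25e-05; both adjusted p = 0.651 with an estimated correlation). Magel2, an imprinted gene of hypothalamic neurons, rose 2.00-fold (1.00, SE 0.24, adjusted p = 0.021), and the appetite peptide gene Npy had a log2 change of -0.73 (SE 0.17, adjusted p = 0.0154), each lost without any 1 of 4 arrays.

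In the G9a hypothalamus, 4 against 4, 273 of 11738 genes changed, 186 up and 87 down. Nxf3 rose at least 3.67-fold (4.13, SE 0.24, adjusted p = 1.4e-18), Dach2 17-fold (4.09, SE 0.22), Adh6b at least 4.17-fold (3.75, SE 0.21), Myh1 at least 4.35-fold, Gsta2 at least 2.20-fold and Ttn at least 4.5-fold. Slc5a5 fell 4.44-fold (-2.15, SE 0.20, adjusted p = 4.78e-11), the scavenger receptor gene Scarf2 at least 1.40-fold (-1.46, SE 0.19), Amn 2.63-fold and Ehmt2 2.03-fold (-1.02, SE 0.14), with Rpp25 (-1.26), Rspo1 (-0.95), Mkx (-0.94, lost without any 1 of 4 arrays) and Kazald1 (-0.91). Gh, growth hormone of the pituitary, was at least 15.5-fold higher in the mutant mean (5.01, SE 1.42, adjusted p = 0.0438) and the dopamine receptor gene Drd1 2.16-fold higher (1.11, SE 0.18, adjusted p = 7.33e-05), both with overlapping arrays. Gh lost its call in 4 other settings and without any 1 of 4 arrays. Of 4 pituitary genes Gh alone passed (list adjusted p = 0.0384; adjusted p = 0.952 with an estimated correlation). Muscle genes had 5 of 15 up and 1 down, the glycogen phosphorylase gene Pygm, or 5 up and 2 down when adjusted over the list alone (adjusted p = 0.0311; adjusted p = 0.952 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 43 up and 2 down (adjusted p = 7.23e-05) and the mitochondrial respiratory chain 0 of 85 up and 1 down (adjusted p = 0.000617), both with adjusted p = 0.952 with an estimated correlation.

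The G9a hypothalamus count depended on which arrays were kept. Mutants 3 and 4 had Gapdh 3-prime to 5-prime log2 ratios of 4.39 and 4.02, against 1.63 to 2.36 in the other arrays of this comparison, a sign of RNA quality. Without both, 522 genes changed, 226 up and 296 down, of which 121 were among the 273. By Xist and Y-linked genes mutants 3 and 4 matched males, and the mutants left matched females, against controls of both sexes. Genotype and sex are therefore not separate in the 522. Without mutant 2 the count was 2052, without control 1 546, without control 2 145, without control 3 137, with the G9a hypothalamus arrays alone in the fit 20, and with a fold of at least 1.5 also required 104. GLP and G9a shared 36 genes up in the hypothalamus (1.40 by chance) and 9 down (0.156), with adjusted p of 2.64e-42 and 2.9e-14 and no gene in opposite directions. The correlation across genes was 0.45. Of 12040 genes tested for a difference between the deletions, Ehmt2 alone passed (1.05, adjusted p = 0.0185). That count was 26 with values below the array median set to it, 6 after quantile normalization, 5 without a filter, 4 with all probe sets or the replicate block, 0 with the compared groups alone and 141 without both mutants of high Gapdh ratio. Leaving out 1 array at a time, it was 232 without G9a mutant 2, 20 without G9a mutant 1, 10 without G9a control 1, 9 without G9a mutant 3, 3 without GLP mutant 2 or 3, 2 without GLP control 2, 3 or 4 or G9a control 4, and 0 without G9a control 2 or 3.

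In the GLP striatum, 4 against 4, Ttn, Afp, Dach2 and Corin rose most. Ttn rose at least 37.3-fold (6.47, SE 0.38, adjusted p = 1.22e-18), Afp at least 28.2-fold (6.34, SE 0.31, adjusted p = 7.83e-22), Dach2 at least 36.1-fold (5.99, SE 0.22) and Corin, the protease that activates atrial natriuretic peptide, at least 11.1-fold (5.46, SE 0.24, adjusted p = 5.23e-24). Bank1, a scaffold of B cells, rose 7.21-fold (2.85, SE 0.30), Cd2, of T cells, at least 1.27-fold, and Zranb3, a DNA remodelling enzyme, 4.88-fold (2.29, SE 0.15). Fst fell 5.20-fold (-2.38, SE 0.29, adjusted p = 7.94e-08), Amn at least 1.5-fold, the interleukin 17 receptor gene Il17rc at least 2.74-fold (-1.51, SE 0.15), Reep6 2.73-fold (-1.45, SE 0.18), with Pdgfd (-1.25), Slc5a5 (-1.23), Rps4l (-1.15) and Sycp3 (-1.13). Of 11547 genes 193 changed, 134 up and 59 down, and 113 with these 8 arrays alone in the fit.

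Muscle genes had 4 of 14 up and 0 down in the GLP striatum, or 5 up and 1 down when adjusted over the list alone (adjusted p = 6.83e-07; 0.000719 with an estimated correlation). Of 6 liver and plasma protein genes 1 rose, Afp, and 1 fell, Rbp4 (-0.81, lost without any 1 of 4 arrays), with a median change of -0.14 and a mean of 0.66, and the list was not called (adjusted p = 0.184). Germline genes had 2 of 4 down, Sycp3 and the germ cell RNA-binding gene Dazl (-0.71; list adjusted p = 0.00811; adjusted p = 0.126 with an estimated correlation). Dazl lost its call without any 1 of the 8 arrays, with all probe sets and with the replicate block, and Sycp3 without either of 2 arrays and with values below the array median set to it. Clustered protocadherins had 0 of 12 up, or 3 when adjusted over the list alone (adjusted p = 0.00221; adjusted p = 0.325 with an estimated correlation). Monoaminergic markers had 0 of 6 up, or 3 when adjusted over the list alone (adjusted p = 0.00837; adjusted p = 0.212 with an estimated correlation). Drd1-MSN markers had 1 of 16 up (adjusted p = 0.0318; adjusted p = 0.61 with an estimated correlation). Called down were microglia markers (0 of 22; adjusted p = 0.00561; 0.65 with an estimated correlation), interferon-stimulated genes (0 of 17; adjusted p = 0.00174; 0.55 with an estimated correlation), cytosolic ribosomal proteins (2 of 43 down; adjusted p = 0.00561; 0.835 with an estimated correlation) and the mitochondrial respiratory chain (0 of 85; adjusted p = 7.38e-05; 0.798 with an estimated correlation).

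In the G9a striatum, 4 against 4, 350 of 11569 genes changed, 217 up and 133 down. Ttn rose at least 33.7-fold (6.93, SE 0.38, adjusted p = 8.14e-20), Afp at least 14.8-fold (6.41, SE 0.31, adjusted p = 4.65e-22), Dach2 at least 23.7-fold (5.99, SE 0.22), Corin at least 14.8-fold (5.33, SE 0.24), Bank1 9.05-fold (3.18, SE 0.30) and Cyp2c23, a fatty acid epoxygenase, at least 3.65-fold (3.28, SE 0.21). Fst fell 6.55-fold (-2.71, SE 0.29, adjusted p = 1.76e-09), Reep6 4.15-fold (-2.05, SE 0.18, adjusted p = 3.15e-12), the axon guidance gene Ntng1 2.84-fold, Ryr1, the calcium release channel of skeletal muscle, 2.69-fold, and the neurotrophic factor gene Nrtn 2.44-fold (-1.29, SE 0.19). Ehmt2 fell 2.44-fold, and the cannabinoid receptor gene Cnr1 1.65-fold (-0.72, SE 0.11). Leaving out control 1 gave 224 genes, and requiring a fold of at least 1.5 as well gave 215, 164 of them up.

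Of 18 excitatory projection neuron markers 4 rose in the G9a striatum, or 8 when adjusted over the list alone (adjusted p = 0.000248; adjusted p = 0.332 with an estimated correlation). These were the cortical transcription factor genes Neurod6 (at least 2.39-fold, log2 2.88, SE 0.71, adjusted p = 0.01), Tbr1 (3.96-fold, 1.99, SE 0.55) and Neurod2 (at least 3.30-fold, 1.79, SE 0.40) and the vesicular glutamate transporter gene Slc17a7 (at least 4.01-fold, 2.09, SE 0.62, adjusted p = 0.0471), each with overlapping arrays. Slc17a7 lost its call in 8 other settings and without any 1 of 7 arrays, Tbr1 in 3 settings and without any 1 of 6 arrays, Neurod6 in 3 settings and without any 1 of 3 arrays, and Neurod2 in 1 setting and without 1 array. A mean over 50 genes of higher level in cortex than striatum lay at 1.85 to 2.34 in the mutants, 2.09 in control 3 and 0.77 to 1.06 in the other controls. Nr4a2, an activity-regulated nuclear receptor, was 10.8-fold higher (3.44, SE 0.61, adjusted p = 0.000126), also with overlapping arrays. Muscle genes had 6 of 15 up and 1 down, Ryr1, or 7 up when adjusted over the list alone (adjusted p = 2.06e-05; 0.00182 with an estimated correlation). Liver and plasma protein genes had 1 of 6 up, Afp (adjusted p = 0.00634; 0.0168 with an estimated correlation). Monoaminergic markers had 1 of 6 up (adjusted p = 0.0221; adjusted p = 0.186 with an estimated correlation).

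GLP and G9a shared 96 genes up in the striatum (2.37 by chance, adjusted p = 1.07e-146) and 22 down (0.618, adjusted p = 1.75e-28), and no gene moved in opposite directions. The correlation of the changes across genes was 0.599. The test of the difference between the deletions passed Ehmt2 alone (1.05, adjusted p = 0.018), with 13 genes when values below the array median were set to it, 2 with all probe sets, and 0 with the replicate block or with the compared groups alone. Ehmt1 came next without passing (-0.77, adjusted p = 0.0886). Leaving out 1 array at a time gave 0 genes without GLP control 1, G9a mutant 1, G9a mutant 3 or G9a control 2, and 9 without G9a control 3, 5 without G9a control 4, 4 without GLP mutant 1, 3 without GLP control 2, and 2 without GLP mutant 4, GLP control 4 or G9a control 1.

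In the GLP cortex, 4 against 4, 179 of 11585 genes changed, 153 up and 26 down. Dach2 rose at least 47.1-fold (6.21, SE 0.22, adjusted p = 3.21e-28), Gsta2 at least 5.20-fold (3.90, SE 0.38), Gpr50 at least 3.36-fold, Afp at least 3.65-fold (3.30, SE 0.31, adjusted p = 4.66e-11), Zranb3 7.08-fold (2.82, SE 0.15, adjusted p = 7.27e-21), and the stomach gene Gkn1 (2.99), the calcium pump regulator Sln (2.98) and Gabra6, a GABA receptor subunit of cerebellar granule cells (2.85), with them. Amn fell at least 2.70-fold (-1.80, SE 0.24, adjusted p = 5.78e-07), the antibody heavy chain gene Ighm 3.02-fold (-1.59, SE 0.21), Reep6 2.19-fold (-1.13, SE 0.18), Kazald1 (-1.19), Cd99 (-0.98), Slc5a5 (-0.98), Crlf2 (-0.95) and C1qtnf12 (-0.79). Muscle genes had 6 of 16 up and 0 down, or 9 up when adjusted over the list alone (adjusted p = 1.48e-13; 0.000122 with an estimated correlation). Monoaminergic markers had 3 of 7 up, or 5 when adjusted over the list alone (adjusted p = 1.7e-08; 0.000252 with an estimated correlation), namely Tph2, the serotonin-synthesizing enzyme of neurons (at least 1.42-fold, 1.79, SE 0.38), Aldh1a1 (1.94-fold) and the monoamine oxidase gene Maob (0.66). Liver and plasma protein genes had 2 of 9 up, Afp and Fbp1 (adjusted p = 0.0124; 0.0348 with an estimated correlation), and germline genes 1 of 4 down, Dazl (adjusted p = 0.00802; 0.0398 with an estimated correlation), whose call was lost without any 1 of 4 arrays.

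Further lists were called in the GLP cortex. Pan-MSN markers had 0 of 21 members passing and were called down (adjusted p = 3.39e-06; 0.0398 with an estimated correlation). The H3K9 methylation machinery had 3 of 25 down, Ehmt1 (-0.76), Kdm3b (-0.55) and Kdm3a (-0.44; list adjusted p = 0.0124; adjusted p = 0.177 with an estimated correlation). Neural progenitor and developmental regulators had 1 of 27 up (adjusted p = 0.0124; adjusted p = 0.347 with an estimated correlation), and meningeal and fibroblast markers 0 of 19 (up, adjusted p = 0.0136; adjusted p = 0.795 with an estimated correlation). With these 8 arrays alone in the fit 365 genes changed, 261 up and 104 down.

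In the G9a cortex, with 2 arrays in each group, 86 of 11675 genes changed, 74 up and 12 down. An unadjusted limma p under 0.05 was found for 374 genes, fewer than the 584 expected with no change. Dach2 rose at least 50.7-fold (6.03, SE 0.31, adjusted p = 7.66e-21), Zranb3 10.6-fold (3.40, SE 0.21, adjusted p = 6.49e-18), the sarcomere gene Neb at least 2.52-fold (3.42, SE 0.36), Casp1 at least 7.71-fold (3.05, SE 0.43), Afp at least 3.79-fold (3.37, SE 0.44) and Defb1 at least 6.18-fold. Amn fell at least 3.81-fold (-2.05, SE 0.34, adjusted p = 0.000115), Ehmt2 3.38-fold (-1.76, SE 0.19), Wnt2 at least 1.77-fold, Ighm 2.78-fold, Slc5a5 2.70-fold, Reep6 2.46-fold, C1qtnf12 (-0.82) and Plcxd1 (-0.81). Muscle genes had 3 of 19 up, or 7 when adjusted over the list alone (adjusted p = 5.54e-16; 9.81e-07 with an estimated correlation), liver and plasma protein genes 2 of 7 up (adjusted p = 2.32e-09; 9.81e-07 with an estimated correlation) and monoaminergic markers 1 of 7 up, Aldh1a1 (2.04-fold; list adjusted p = 7.94e-05; 0.0121 with an estimated correlation). The H3K9 methylation machinery had 2 of 25 down, Ehmt2 and Kdm3b (-0.61; list adjusted p = 0.000571; adjusted p = 0.0551 with an estimated correlation). Aldh1a1, Kdm3b, Defb1, Wnt2 and Plcxd1 each lost their call without any 1 of the 4 arrays, Aldh1a1 also with all probe sets and with the filter at 32 times the median.

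Lists with few or no members passing were also called in the G9a cortex, and each lost its call with an estimated correlation. Called up were meningeal markers (0 of 20, adjusted p = 7.56e-09; 0.157 with an estimated correlation), interferon-stimulated genes (1 of 18, Ifih1, lost without any 1 of the 4 arrays, or 2 when adjusted over the list alone; adjusted p = 3.42e-06; 0.132 with an estimated correlation), endothelial markers (0 of 22, adjusted p = 0.0131; 0.646 with an estimated correlation) and the genes next to Camk2a (0 of 11, adjusted p = 0.00176; 0.109 with an estimated correlation). Called down were pan-MSN markers (0 of 21, adjusted p = 0.0117; 0.4 with an estimated correlation), Drd1-MSN markers (0 of 16, adjusted p = 0.0131; 0.405 with an estimated correlation) and oligodendrocyte markers (0 of 25, adjusted p = 0.0131; 0.676 with an estimated correlation). The gene count was 48 and 52 without mutants 1 and 2, 50 and 57 without controls 1 and 2, and 308 with these 4 arrays alone in the fit.

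The cortical lists of GLP and G9a shared 60 genes up (0.806 by chance, adjusted p = 4.19e-114) and 8 down (0.0248, adjusted p = 1.28e-19), none in opposite directions, with a correlation of 0.699 across genes. The shared count of 68 was 38 to 45 without any 1 of the 4 G9a arrays and 153 with the compared groups alone in each fit. A difference between the deletions passed for 2 genes (11 with values below the array median set to it), Ehmt2 (1.65, SE 0.24, adjusted p = 3.55e-05) and Cap1, a regulator of actin turnover, which had changes of -0.14 on loss of GLP and 1.56 on loss of G9a (adjusted p = 5.67e-08). For this difference 122 genes had an unadjusted limma p under 0.05, where 595 are expected with no difference. By Xist and Y-linked genes all GLP cortex arrays matched females and all G9a cortex arrays males, so deletion and sex cannot be told apart in the difference of Cap1. For Ehmt2 the difference also passed in the other regions, where G9a mutants and controls held both sexes.

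Changes differed between regions for 134 of 12418 genes on loss of GLP and 174 of 12688 on loss of G9a (limma's F test of 4 regions). Among GLP mutants, Adh6b rose at least 5.67-fold in the hypothalamus, where Ehmt1 itself did not pass as lower. Elsewhere Adh6b lay below the array median in mutants and controls (adjusted p = 1.31e-16). Afp rose at least 28.2-fold in the striatum and 3.65-fold in the cortex, and lay below that median in both groups of the hippocampus and hypothalamus (adjusted p = 2.66e-15). Corin, Nxf3, Zranb3 and Cd2 also differed (highest adjusted p = 1.47e-12). After loss of G9a, Gprc5d rose at least 1.93-fold in the hippocampus and lay far below the array median elsewhere, at -3.75 to -2.99 in mutants and controls (adjusted p = 3.61e-18). Corin, Afp, Adh6b, Ttn and Cyp2c23 differed too (highest adjusted p = 2.44e-12). The count for G9a was 586 without hypothalamus mutant 2. Between regions, the hippocampus and cortex shared 65 genes changed the same way on loss of GLP, as did the striatum and cortex. Arrays of different regions may share animals, so these lists need not be independent.

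In polyribosome RNA of Drd1-MSN, 3 pools labelled mutant against 3 controls, Afp rose 72.0-fold (6.17, SE 0.50, adjusted p = 0.000224), Dach2 53.2-fold (5.73, SE 0.45, adjusted p = 0.000224) and Bank1 7.37-fold (2.88, SE 0.40, adjusted p = 0.0445; lost in 4 other settings and without any 1 of 5 arrays), and no other of 12116 genes passed. At an unadjusted p under 0.05 there were 285, fewer than the 606 expected with no change. All 3 also rose in the whole striatum on loss of G9a. Zranb3 (2.60, SE 0.39, adjusted p = 0.0539) and Cabp5 (2.12, SE 0.31, adjusted p = 0.0534) did not pass. Oligodendrocyte markers (0 of 25) and thalamus markers (0 of 17) were called down as lists (adjusted p = 0.0287 and 0.017; both adjusted p = 0.877 with an estimated correlation). Mutant and control pools differed in sex mix: the Y-linked gene Eif2s3y stood at 4.24 and 4.47 in mutants 1 and 3, at -0.22 in mutant 2 and at -1.66, -1.09 and 0.34 in controls 1 to 3. Genotype and sex mix are therefore not separate in this comparison. The count was 9 without mutant 2, 5 without mutant 1 and 0 with these 6 arrays alone in the fit. Mutant 2 stood farthest from its group (SD of differences 0.82 on the log2 scale), and without it and Drd2-MSN control 1, whose Gapdh 3-prime to 5-prime log2 ratio was 4.95, 10 genes rose.

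In polyribosome RNA of Drd2-MSN, 3 pools labelled mutant, whose Ehmt2 level goes against that label, against 3 controls, Afp rose 101-fold (6.66, SE 0.50, adjusted p = 0.000193) and Dach2 at least 7.94-fold (3.74, SE 0.45, adjusted p = 0.0166), and no other of 12126 genes passed. Both genes also rose in the whole striatum on loss of G9a, which goes with the label. At an unadjusted p under 0.05 there were 174, where 606 are expected with no change. Bank1 (2.70, SE 0.40) and Serpinb1b (1.72) had an adjusted p of 0.0638, and Gbe1 (2.04) of 0.133. Liver and plasma protein genes had 1 of 10 up, Afp (adjusted p = 0.0095; adjusted p = 0.147 with an estimated correlation). Choroid plexus markers (0 of 11, or 1 when adjusted over the list alone; adjusted p = 0.000203; 0.147 with an estimated correlation), microglia markers (0 of 19; adjusted p = 0.0288; 0.601 with an estimated correlation) and cytosolic ribosomal proteins (0 of 42; adjusted p = 0.0111; 0.714 with an estimated correlation) were called up as lists. Excitatory neuron markers (0 of 18; adjusted p = 0.0111; 0.601 with an estimated correlation) and glutamate receptors (0 of 34; adjusted p = 0.0111; 0.714 with an estimated correlation) were called down. With pools paired by number as a block, 1 gene passed and Dach2 lost its call, and 1 gene passed without the pools labelled mutant 2 or mutant 3 or any single control.

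Afp and Dach2 were the 2 genes higher in the pools labelled mutant of both cell types, where independent lists would share 0.000516 (adjusted p = 4.96e-08). The changes of the 2 cell types had a correlation of 0.0406 across genes. No gene passed limma's test of a difference between Drd1-MSN and Drd2-MSN in the change from controls to pools labelled mutant (0 of 12694). At an unadjusted p under 0.05 there were 175, where 635 are expected with no difference, and Ndnf came nearest (-4.78, SE 0.87, adjusted p = 0.969). The count was 2 without Drd1-MSN mutant 2 and 1 without Drd1-MSN mutant 1. The shared count was 1 without the Drd2-MSN pools labelled mutant 2 or mutant 3 or any 1 of its controls, 1 with pools paired by number as a block, and 0 with the compared groups alone in each fit.

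Between control pools of the 2 cell types, 3 against 3, 995 genes were higher in Drd1-MSN and 939 in Drd2-MSN, of 12301. Of 16 Drd1-MSN markers 5 were higher in Drd1-MSN and 0 lower, and of 17 Drd2-MSN markers 5 were lower and 0 higher, with the same counts adjusted over the list alone. Eya1 (19.7-fold, log2 4.30, SE 0.48, adjusted p = 0.000175), the opioid peptide precursor Pdyn (3.22-fold), Sfxn1 (3.11-fold) and the substance P precursor Tac1 (1.76-fold) were higher in Drd1-MSN. Pdyn lost its call with pools paired by number as a block. Higher in Drd2-MSN were Drd2 (7.14-fold, -2.83, SE 0.39, adjusted p = 0.000703), Gpr6 (2.49-fold) and the enkephalin precursor Penk (2.09-fold, -1.06, SE 0.23). Large differences toward Drd1-MSN included Acsm2 (at least 19.8-fold, 7.31, SE 0.44), the amino acid transport gene Cltrn (at least 38.9-fold), Umod, the most abundant protein of urine (at least 31.2-fold, 6.64, SE 1.25, adjusted p = 0.00476), Fbp1 (at least 16.2-fold), Gpx3 (at least 16.4-fold) and Miox (at least 5.63-fold). Lower in Drd1-MSN were the splicing regulator Ptbp1 (48.5-fold, -5.60, SE 0.85) and Ttc12, which lies next to Drd2 (41.9-fold, -5.39, SE 0.79). Eif2s3y, on the Y chromosome, was at least 12.1-fold lower (-4.39, adjusted p = 0.0222). It stood at -1.66, -1.09 and 0.34 in Drd1-MSN controls 1 to 3 and at 3.02 to 4.67 in Drd2-MSN controls. Cell type and sex mix are therefore not separate in this comparison. Of 18 microglia and macrophage markers 7 were lower in Drd1-MSN and 1 higher, or 9 and 2 when adjusted over the list alone, with Csf1r (-1.71, lost without any 1 of 4 arrays) and Tyrobp (-1.57) among the lower. Of 87 genes of the mitochondrial respiratory chain 35 were higher in Drd1-MSN and 1 lower, or 52 and 1 when adjusted over the list alone, with a median difference of 0.62 (0.32 after quantile normalization). The count of 1934 was 1012 without Drd1-MSN control 2, 1079 without Drd1-MSN control 3, 1153 with pools paired by number as a block and 3441 without the pair of arrays that stood apart. After quantile normalization 40.6% of 1871 genes were higher in Drd1-MSN, against 51.4% of the 1934.

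**Figure D3:**
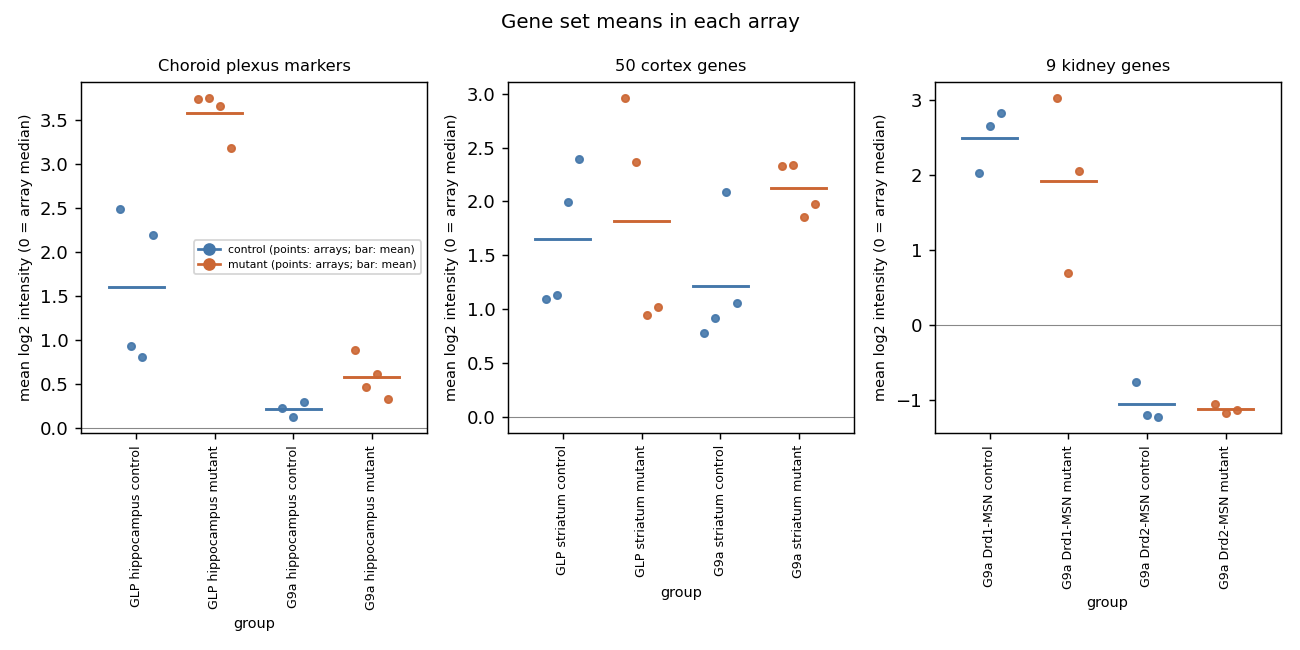
Mean log2 intensity relative to the array median (y axis) of 3 gene sets in each array (points) of the groups compared (x axis), with group means as bars: choroid plexus markers in the hippocampus, 50 cortex genes in the striatum, and 9 kidney genes that were higher in Drd1-MSN controls in the polyribosome arrays. The choroid mean lay at 3.18 to 3.74 in GLP hippocampus mutants, and the cortex mean at 1.85 to 2.34 in G9a striatum mutants.

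Over the 333 list tests of the 10 mutant comparisons, camera called 64, of which 17 held with an estimated correlation, and fry, which tests each list on its own, called 28. Muscle genes were called up in all 8 tissue comparisons, and held with an estimated correlation in 7. Of 48 muscle genes on the arrays, 13 to 19 were measured in these comparisons. Those silent in controls passed the filter only where they rose, so the filter favours rises. How far that made these calls was not tested. The same limit holds for liver and plasma protein genes. In none of the 10 comparisons did camera call the genes next to Drd1 (lowest adjusted p = 0.0719), immediate early genes (0.0748), imprinted genes (0.082), hypothalamic peptides (0.132), the genes next to Ehmt2 (0.155), Drd2 (0.212) or Ehmt1 (0.245), hippocampal subfield markers (0.234), GABAergic interneuron markers (0.265) or cholinergic neuron markers (0.312).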

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

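The test on the correlation of choroid plexus markers was chosen only after the result was seen, as was how far the adjusted change in both covariate tests had to lie below 0. Of 415 groups of 4 arrays examined for the genes, lists and quality measures named in the text, 28 held 1 array far from the other 3, where chance alone gives about 1 in 20 groups.

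Control 3 of the G9a striatum stood apart most often, in 6 of these 28 cases. It stood at 2.44 on the log2 scale for Neurod6, where the other controls lay at -3.13 to -2.69, at 2.69 for Slc17a7 (others -1.14 to -0.87), at 2.70 for Tbr1 (others -0.50 to -0.14), at 5.92 for Nr4a2 (others 0.88 to 1.04) and at 4.11 for the mean of excitatory projection neuron markers (others 2.77 to 2.98). Ehmt2 stood at 4.77 in that array, below the other controls at 5.41 to 5.52. Without control 3, 299 genes changed, of which 267 were among the 350, and the change of Neurod6 went from 2.88 to 4.23.

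Cortical projection neuron genes were higher in the G9a striatum mutants, and more cortex in the mutant samples is a candidate explanation. Of the 50 genes with the largest excess of cortex over striatum in GLP controls, 47 were higher in the G9a striatum mutants, by a median of 0.75, and 17 passed the test, while 35 of them were higher in GLP striatum mutants (median 0.17). That outcome could have been otherwise, although 6 of the projection neuron markers are among the 50 genes. An effect of G9a loss apart from cortex content remained open: with the mean of the 50 genes as a covariate 0 of 4 called markers passed, and their median change of 2.04 (SE 0.58) became -0.40 (SE 0.77). The adjusted change lies within 1 SE of 0, so it does not exclude such an effect.

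Choroid plexus genes were higher in the GLP hippocampus mutants, and more choroid plexus in those samples remained open as a candidate explanation. The mean correlation of the markers within groups was 0.644, where 1000 random lists of the same size had a median of 0.111 and an upper limit of 0.272, so their level varied together from array to array. That does not say what raised them in the mutants, and 0 of 4 controls reached the lowest mutant (2.49 against 3.18). The same mean differed between arrays of equal genotype in the G9a striatum controls, at -0.13, 2.33, 2.10 and 3.55. In the G9a hippocampus it lay at 0.13 to 0.29 in controls and 0.33 to 0.89 in mutants. The level of these markers can thus vary without a difference in genotype, which does not decide what raised them in the GLP hippocampus. An effect of GLP loss apart from choroid content remained open too. With the mean of the other markers as a covariate 0 of 16 called markers passed, and their median change went from 2.37 (SE 0.50) to -0.05 (SE 0.94), again within 1 SE of 0.

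In the GLP hippocampus mutants, array 4 stood apart for Folr1 (3.94, others 4.76 to 4.83), Slc5a5 (1.41, others 0.91 to 0.97) and Tmprss11a (1.49, others 2.03 to 2.09), array 1 for Cst12 (1.88, others 2.18 to 2.22) and Igf2 (5.95, others 5.35 to 5.44), and array 2 for the mean of microglia markers (3.60, others 3.29 to 3.32). In the GLP hypothalamus, Cda was -1.13 in mutant 2 and 1.25 in control 2, and Crlf2 was 0.64 in mutant 3. In the GLP striatum, Cd2 was -3.10 in control 3, below the array median as in every control there. In the GLP cortex, Crlf2 was 1.27 and Kazald1 -0.74 in mutant 3, Kdm3b was 2.28 and Reep6 1.16 in mutant 1, Kdm3b was 2.86 in control 2 and C1qtnf12 was 4.40 in control 4. Chrna1 was 1.49 in G9a hippocampus mutant 3 and Pla2g5 -1.88 in mutant 1. In the G9a hypothalamus, Kazald1 was 0.40 in mutant 4, Nxf3 1.33 in mutant 1, and the Gapdh log2 ratio 2.05 in control 1, against 1.63 to 1.70 in the other controls. Cnr1 was 6.61 in G9a striatum mutant 3, where the other mutants lay at 7.14 to 7.17.

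The effect of GLP loss differed from that of G9a loss, by limma's interaction test, in the hippocampus for Gprc5d (difference -2.80), Tshz2 (-2.15), Ido2 (-2.03), Cobl (-1.74), Pla2g5 (1.61) and Ehmt2 (1.04). Gprc5d and Ido2 on loss of GLP, and Pla2g5 on loss of G9a, lay under the low-value filter. Ehmt2 also differed in the hypothalamus (1.05), striatum (1.05) and cortex (1.65), and Cap1 in the cortex (-1.70), where the GLP arrays matched females and the G9a arrays males, so that sex remained open for Cap1. In the hippocampus the GLP arrays matched females while the G9a arrays held both sexes, so sex was not balanced there either. The mean of choroid plexus markers was also higher in the GLP mutants of that region, and its part in these differences was not tested. Between the 4 regions, 134 genes differed in the effect of GLP loss and 174 in that of G9a loss.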

How the results depend on the processing

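The tests with the first planned filter and floor, without both arrays of high Gapdh ratio, and without both polyribosome arrays that stood apart were chosen only after the data were seen. Of 540 values for named genes, 483 were past the threshold, and 276 of these stayed past it in every setting in which they could be tested. No called value reversed its direction in these settings. Of the 483, the calls lost were 94 with only the compared groups in the fit, 61 with the replicate number as a block, 37 with the first planned floor, 35 with a fold of at least 1.5, 25 with all probe sets, 21 after quantile normalization, 14 without a filter and 9 without an intensity trend. The first planned filter ended 10 of the 66 it could test, a sex covariate 11 of 164 and leaving out 1 array 608 of 3429. Leaving out both arrays of high Gapdh ratio ended 8 of 39, and both polyribosome arrays that stood apart 3 of 108. The number of arrays, and signals near the array median, limit these values. Where a count moved below, the cause was not tested, apart from fewer genes or fewer arrays in the test.

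With the first planned filter, 32 times the array median, far fewer genes were tested. Counts were 14, 4, 16 and 7 for loss of GLP in the hippocampus, hypothalamus, striatum and cortex, and 18, 41, 58 and 4 for loss of G9a in the same order. In the G9a striatum 36.2% of calls were then up, against 62.0%. Drd1-MSN and Drd2-MSN gave 1 gene each and 1 shared gene, and their controls differed in 761 genes. The genes shared by GLP and G9a were 5 in the hippocampus, 1 in the hypothalamus, 9 in the striatum and 1 in the cortex. The interaction in the hippocampus gave 1 gene, and the tests across regions 13 (GLP) and 27 (G9a). With values below the array median set to it, the interactions gave 58 genes in the hippocampus, 26 in the hypothalamus, 13 in the striatum and 11 in the cortex, the test of GLP across regions 263, Drd2-MSN 1 and the shared Drd1-MSN and Drd2-MSN genes 1. Without any filter, the controls of the cell types differed in 4426 genes, the interactions gave 37 genes in the hippocampus and 5 in the hypothalamus, GLP and G9a shared 75 genes in the hypothalamus, and 210 genes differed across regions on loss of GLP.

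With only the compared groups in the fit, counts were 39, 113 and 365 for loss of GLP in the hypothalamus, striatum and cortex and 188, 20 and 308 for loss of G9a in the hippocampus, hypothalamus and cortex. Drd1-MSN then gave 0 genes, with 0 shared with Drd2-MSN, GLP and G9a shared 14 genes in the hypothalamus and 153 in the cortex, and the interactions gave 7 genes in the hippocampus and 0 in the hypothalamus and striatum. With all probe sets tested, counts were 498 in the G9a hypothalamus, 537 in the G9a striatum, 4 in Drd2-MSN, 4 shared by both cell types, 4297 between their controls, and 4 and 2 for the interactions in the hypothalamus and striatum. A fold of at least 1.5 left 104 genes in the G9a hypothalamus and 215 in the G9a striatum. Quantile normalization gave 479 in the G9a hypothalamus, 4 in Drd2-MSN and 6 for the interaction in the hypothalamus. Camera with an estimated correlation called 17 lists and fry 28, against 64.

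In Drd2-MSN alone did all pairs of equal number correlate above 0.1 across genes. Its 3 pairs lay at 0.168 to 0.482, with each pool closest to its own number. Elsewhere the lowest correlation of a pair was -0.302 to 0.0628. With the replicate number as a block, paired by number, counts were 460 in the G9a hypothalamus, 1 in Drd2-MSN, 1 shared by both cell types, 1153 between their controls, and 4 and 0 for the interactions in the hypothalamus and striatum. No other count moved by over 1.5 times. As a hint from the data, 3 of 4 pairs in the G9a hypothalamus were closest to their own number. The number of control 4 there is uncertain, as its source name says mouse 5, so neither the 460 nor these pairs are sure. Treating arrays of equal number in different regions as a random block (consensus correlation 0.0396) moved neither count across regions by over 1.5 times.

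Without mutants 3 and 4 of the G9a hypothalamus, whose Gapdh ratio was high, 522 genes changed and the interaction in the hypothalamus gave 141. The G9a mutants left matched females, while the G9a controls held both sexes, so sex is mixed with genotype in both counts. Without Drd1-MSN mutant 2 and Drd2-MSN control 1, Drd1-MSN gave 10 genes and the controls 3441. Leaving out 1 array at a time, counts lay between 80 and 202 in the GLP hypothalamus, 192 and 364 in the G9a hippocampus, 137 and 2052 in the G9a hypothalamus, 224 and 381 in the G9a striatum, 48 and 57 in the G9a cortex (where the lone array left is assumed to vary like the other groups), 2 and 9 in Drd1-MSN, 1 and 2 in Drd2-MSN, and 1012 and 1613 between their controls. They lay between 1 and 2 for genes shared by Drd1-MSN and Drd2-MSN, 38 and 71 for those shared by GLP and G9a in the cortex, 141 and 586 for G9a across regions, and, for the interactions, 8 and 39 in the hippocampus, 0 and 232 in the hypothalamus, 0 and 9 in the striatum and 0 and 2 in the cell types. The other counts stayed within 1.5 times: 177 to 240 in the GLP hippocampus, 147 to 181 in the GLP striatum, 144 to 179 in the GLP cortex, 113 to 172 for GLP across regions, and 86 to 106, 35 to 58 and 95 to 121 for the genes shared in the hippocampus, hypothalamus and striatum.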

Other observations

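The tests of other splits of the arrays for single comparisons, interactions and regions in this part were chosen only after the result was seen, as were the restriction to splits that part every pair, the setting of low levels to the array median and the count of kidney markers without a filter. Between the control pools, 6 of 17 thalamus markers were higher in Drd1-MSN and 0 lower, among them Shox2 (at least 5.53-fold), Prkcd (log2 2.91), the vesicular glutamate transporter Slc17a6 (2.24) and Ntng1 (2.02). Prkcd, Slc17a6 and Ntng1 lost their calls with pools paired by number as a block and without any 1 of 4 arrays, and Slc17a6 also without both arrays that stood apart. Lower in Drd1-MSN were the forebrain cholinergic regulator Lhx8 (-1.91), the gap junction gene Gjb1 (-2.86) and the myelin lipid enzyme Fa2h (-1.77), while the MSN genes Gnal (4.06-fold) and Arpp21 (0.57) were higher there, a call that Arpp21 lost in 4 settings, among them the block, and without any 1 of 3 arrays. In the G9a hypothalamus, mutant 2, without which 2052 genes changed, had an SD of differences from its group of 0.471, against 0.158 to 0.290 in the other arrays of that comparison. By Xist and Y-linked genes, all GLP arrays matched females and all G9a cortex arrays males, and the other G9a tissues held both sexes in both groups.

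Kidney genes were higher in Drd1-MSN pools than in Drd2-MSN pools, and RNA from kidney in those pools is a candidate source. Of 24 kidney markers written down before the test, 4 had been seen first, and of 9 others past the low-value filter 5 were higher in Drd1-MSN controls, but 4 of the 5 lay below the array median in Drd2-MSN controls and the filter favours such genes. Without a filter, 9 of the 16 others on the arrays were higher and 0 lower, 2 of the 9 with levels below the array median in both, where 14.7% of all genes were higher. Umod stood at 4.96 and Kap at 4.62 in Drd1-MSN controls, against -1.68 and 0.40 in Drd2-MSN controls. The mean of the kidney genes in the figure was 0.69 in Drd1-MSN mutant 2 and 2.03 to 3.03 in the other Drd1-MSN pools. Of the 24 markers, 5 lay above the array median in whole striatum and 2 are in another fixed list. The antibody pull-down is meant to remove RNA without the tagged ribosomes, but how fully it did so was not tested. Expression in Drd1-MSN themselves remained open: the median excess of the 9 higher kidney genes over whole-striatum controls was 3.26 (2.03 with levels below the array median set to it), but 7 of the 9 lay below the array median there and the 9 were chosen as higher, so it decides nothing.

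The arrays of each comparison were also split in the other ways that keep the group sizes. In 35 splits of the 8 arrays, or of the 7 in the G9a hippocampus, only the real split gave as many genes in the GLP hippocampus (242, highest other 26), GLP cortex (179, highest other 16), G9a hippocampus (323, highest other 177) and G9a striatum (350, highest other 42), so chance was excluded at the level of 1 in 35. In the GLP striatum 2 splits did (193, highest other 211), in the GLP hypothalamus 5 (118, highest other 729) and in the G9a hypothalamus 14 (273, highest other 3724), so chance was not excluded there. Splits with several times the real count point to a structure of the hypothalamic samples. For Drd1-MSN (3 genes, highest other 0), Drd2-MSN (2, highest other 1) and their controls (1934, highest other 0) the 10 splits, of which 1 gave as many, are too few.

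Of 100 splits each, 1 gave as many genes shared by GLP and G9a in the hippocampus (105, highest other 3) and striatum (118, highest other 0). That share of 1 in 100 is the lowest these splits can give, so chance was unlikely for these counts. In the hypothalamus 3 splits gave as many (45, highest other 67). As another split gave more shared genes than the real one, chance was less likely but not firmly excluded there. Drd2-MSN pools pair by number, so of its 10 splits only the 4 that part every pair were combined with those of Drd1-MSN. Of these 80 combinations 1 gave as many shared genes (2, highest other 0), while 1 gene was shared with the block. For differences between effects such splits decide nothing, because a split can keep the effect of 1 arm that the real difference subtracts. As many genes came from 13 of 100 splits for the interaction in the hippocampus (19, highest other 250), 73 in the hypothalamus (1, Ehmt2 itself, highest other 3167), 32 in the striatum (1, Ehmt2 itself, highest other 380) and 2 for GLP across regions (134, highest other 258). For the cell types all 100 did, as they must for a count of 0. Groups of 2 arrays, and with them the G9a cortex, its interaction, its shared genes and G9a across regions, were not split.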
